A study of Mus musculus with 4 samples.

How the data were processed

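RNA was measured by sequencing in 4 samples of mouse acute myeloid leukemia (AML) cells from bone marrow, sorted as leukemia stem cells (LSCs) that carried a yellow fluorescent protein, the myeloid surface protein Mac-1 and the receptor c-Kit. Per the labels, 2 samples were wild type and 2 were B7-H4-null, all on the C57BL/6 strain. Libraries followed the Illumina TruSeq RNA version 2 protocol, which selects RNA with a poly(A) tail and does not mark strand, and were read on a HiSeq2500. The submitters' processing notes name TopHat2 2.0.12 as the aligner and the build GRCm38. The counting program, its gene annotation and its strand setting are not given in the sources used here, so reads of a gene and of an overlapping antisense gene cannot be told apart.

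The authors deposited 1 table with a column per library and a row per Entrez gene ID, 27179 genes in all, whose values are RPKM, reads scaled to gene length in kilobases and to the library's total. This unit was taken from the values, because the column sums lie between 521931 and 558518 and the low values of each gene are whole multiples of a step that depends on the gene. Whether reads or fragments were counted is not given in the sources used here. Symbols came from an NCBI gene table of GRCm38.p6 for 25275 IDs and from GENCODE tables for 18 more, and 1886 IDs had no symbol. Coordinates are those of that NCBI table on GRCm38.p6.

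The steps between low values gave the total behind the scaling of each library, 10144166 and 9933947 reads for wild type replicates 1 and 2, and 9419425 and 10814448 reads for B7-H4-null replicates 1 and 2. With these totals, 14606 of the 14608 genes above 0 in every library came out as whole reads to within 0.001 read. Summed over genes, the recovered reads exceeded the totals, and the cause was not tested. At this depth 1 read in a gene of 2 kb was worth 0.0462 to 0.0531 RPKM, and 3 reads 0.139 to 0.159 RPKM. A gene with no read in a group was compared with a floor of 3 reads over the group, and a gene with 1 to 3 reads was given as a ratio of reads with its exact 95% binomial interval. Such floors and intervals cover counting error only.

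Genes at 1 RPKM or more in at least 2 of the 4 libraries were tested, 12107 genes. The test was limma 3.58.1 in R 4.3.3, applied to log2(RPKM + 1) with genotype as the only term, a mean-variance trend, two-sided moderated tests and Benjamini-Hochberg adjustment at 0.05. A log2 difference on this scale understates the change of genes at low values, so means in RPKM stand beside it. The design fixed in advance named a count-based test in case the table held raw counts, which it did not. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. An exact permutation test of 2 against 2 samples cannot go below p = 0.33, two-sided, so none was used.

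Before the data were examined, 35 gene lists were written, covering signalling, lineage, cell cycle, metabolic and stress programs and markers of other cell types. Of their 1135 genes, 61 were matched through an older symbol and 19 were not in the table. The 31 lists with at least 5 tested members were tested against all other genes with limma's camera at a preset correlation of 0.01, and the p-values were adjusted over these lists. Camera with an estimated correlation and limma's fry, whose directional p asks whether members move one way on balance and whose mixed p asks whether they change in either direction, were alternatives. The 4 lists with fewer tested members, the sort markers, the erythroid genes, the T and NK cell genes and the X inactivation and Y-linked genes, are given as values only.

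The genes named were chosen by a rule fixed in advance. It takes Vtcn1, Akt1, Akt2, Rcor2 and Runx1 whatever their values, and some further items of the rule and of the lists are not reported here. Per direction it then takes the 10 genes with the largest log2 difference among those past the threshold, with a mean of at least 5 RPKM in the higher group and no overlap between groups. Gene models (names such as Gm or Rik, or a bare number), ribosomal RNAs, snoRNAs, microRNAs and pseudogene symbols are passed over. Where fewer than 5 qualify, the direction is filled to 10 by the smallest p under the same conditions. Of each list spoken of, up to 4 members with the smallest p are named, and members of the check lists with a mean of at least 5 RPKM may be added. Genes named outside the rule are marked as chosen after their values were seen.

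The test was checked on reads simulated for the real genes from the wild-type means, the real totals and the spread between replicates, in 10 runs with 200 changed genes each and 12044 genes tested on average. It recovered 3 of 671 genes changed 2-fold (0.447%), 171 of 660 changed 4-fold (25.9%) and 552 of 669 changed 8-fold (82.5%). Of 778 calls, 52 were false (6.68%). With no changed gene it called 0.2 genes and 0 lists on average over 10 runs. A list shifted 2-fold was called in 5 of 5 runs. Each gene was drawn independently, so the simulated lists held no correlation between members. The simulation therefore cannot show how often a list of correlated genes is called without a change.

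The alternatives fixed in advance were a pseudocount of 0.1, no filter, a filter at 5 RPKM, median-ratio scaling, quantile normalization, the replicate number as a block, each library left out in turn, limma without the trend or with robust variances, and the other list tests. Limma's voom on the recovered reads, and a fit of protein-coding genes without replication-dependent histone and mitochondrially encoded genes after median-ratio scaling, were added after seeing the data. Where a library is left out, the lone library of its group is assumed to vary like the other group. Tables were handled and plots drawn with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.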

Results

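The series holds RNA-seq of LSCs, the cells held to sustain an AML, from 2 wild-type and 2 B7-H4-null samples. B7-H4, encoded by Vtcn1, is a ligand of the B7 family and restrains T cells. The comparison asks which genes differ in expression between the genotypes. The library totals behind the RPKM values lay between 9419425 and 10814448 reads, and 11814 to 11871 genes reached 1 RPKM per library. Across the 12107 tested genes, Pearson's r was 0.957 between the wild-type libraries and 0.948 between the B7-H4-null libraries. Between libraries of different genotype it was 0.909 to 0.95. B7-H4-null replicate 2 was about as close to wild type replicates 1 and 2 (0.95 and 0.946) as to B7-H4-null replicate 1. Genes are not independent replicates, so these values describe the libraries only.

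Vtcn1 (gene ID 242122, chromosome 3, 100825459 to 100896922) was read too rarely to check the genotype labels. It had 0 reads in both wild-type libraries and 2 reads over the B7-H4-null libraries, at 0.0405 and 0.0353 RPKM, so a loss of its transcript was not detectable at this depth. The surface markers of the sort were present in every library. Kit, the receptor c-Kit, stood at 24.0 and 7.19 RPKM in wild type and at 11.02 and 9.37 RPKM in B7-H4-null, a log2 difference of −0.36 (adjusted p = 0.808, limma) that was 0.45 without wild type replicate 1 and −1.16 without wild type replicate 2. Itgam and Itgb2, which together encode Mac-1, had means of 100.5 ± 19.2 and 213 ± 0.197 RPKM in wild type and of 71.4 ± 16.3 and 135 ± 16.3 RPKM in B7-H4-null (SD, n = 2), with adjusted p = 0.556 and 0.371.

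Of the 12107 genes, 5 rose and 7 fell in B7-H4-null LSCs. The split of wild type replicate 1 and B7-H4-null replicate 2 against the others gave 7 called genes, and the remaining split 0. A gene call here is therefore not particular to the genotype split. Mt2, a metallothionein that binds zinc and copper, rose from 6.83 ± 3.65 to 256.7 ± 123.8 RPKM, 37.6-fold in means. Vill, a villin-like actin-binding protein, rose from 2.71 ± 1.06 to 49.2 ± 0.769 RPKM. Eya1, a transcriptional coactivator of the eyes absent family, fell from 32.7 ± 11.6 RPKM to 1 read over both B7-H4-null libraries. Skida1, which carries a SKI/DACH domain, fell from 13.01 ± 2.58 to 0.0228 ± 0.00222 RPKM. All values are mean ± SD with n = 2 per genotype, and each of the 12 genes differed the same way in 2 of 2 B7-H4-null libraries against both wild-type libraries. Leaving out either B7-H4-null library ended all 12 calls, with 0 genes called, while the log2 differences stayed about as large. Without B7-H4-null replicate 1 or 2 they were −5.00 and −5.03 for Eya1, −3.77 and −3.76 for Skida1 and 3.80 and 3.77 for Vill, and Mt2 moved most, to 4.52 and 5.54.

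Among the genes that rose, Mt2 (gene ID 17750, chromosome 8, 94172618 to 94173567) had a log2 difference of 5.03 ± 0.453 (SE, adjusted p = 0.0219), with 344.3 and 169.1 RPKM in the B7-H4-null libraries. Vill (gene ID 22351, chromosome 9, 119052729 to 119071525) had a log2 difference of 3.79 ± 0.285 and was 18.2-fold higher in means (adjusted p = 0.0136). Tdrd9, a tudor-domain helicase known from transposon silencing in the germ line (gene ID 74691, chromosome 12, 111971488 to 112068854), had 0.041 and 0.0419 RPKM in wild type and 7.13 and 7.58 RPKM in B7-H4-null. That is 4 against 717 reads, 177-fold in means, with a log2 difference of 3 ± 0.258 (adjusted p = 0.0183). Chchd10, a protein of the mitochondrial intermembrane space (gene ID 103172, chromosome 10, 75933130 to 75937750), rose 6.93-fold, from 2.89 ± 0.117 to 20.02 ± 2.03 RPKM, with a log2 difference of 2.43 ± 0.244 (adjusted p = 0.0318, and 0.0603 with voom). The other gene that rose is the gene model Gm128 (gene ID 229588, chromosome 3, 95236919 to 95241635), named after its values were seen. It lies 5.58 Mb from Vtcn1, and had 0.335 and 0.205 RPKM in wild type and 7.22 and 8.87 RPKM in B7-H4-null, with a log2 difference of 2.83 ± 0.267 (adjusted p = 0.0261).

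Among the genes that fell, Eya1 (gene ID 14048, chromosome 1, 14168953 to 14311035) had 40.9 and 24.6 RPKM in wild type, or 2864 reads, and a log2 difference of −5.02 ± 0.312 (SE, adjusted p = 0.00862). Its ratio of reads was 2890, with an exact 95% interval of 518 to 114000. Skida1 (gene ID 72668, chromosome 2, 18044087 to 18048449) had 1138 against 2 reads, a ratio of 573 with an exact 95% interval of 158 to 4740, and a log2 difference of −3.76 ± 0.272 (adjusted p = 0.0136). Psma8, a proteasome subunit known from the testis (gene ID 73677, chromosome 18, 14706135 to 14762301), had 8.48 ± 0.458 RPKM or 288 reads in wild type and 0 reads in B7-H4-null. It was at least 96.8-fold lower there against a floor of 3 reads over the group, with a log2 difference of −3.24 ± 0.257 (adjusted p = 0.0154).

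Ces1d, Hpse2 and Hnmt also fell. Ces1d, a carboxylesterase with close paralogs that can share its reads (gene ID 104158, chromosome 8, 93166072 to 93197804), went from 14.8 ± 3.04 to 0.364 ± 0.249 RPKM, 40.5-fold lower (adjusted p = 0.0157). Hpse2, a relative of heparanase (gene ID 545291, chromosome 19, 42786541 to 43388476), went from 10.3 ± 2.37 to 0.509 ± 0.178 RPKM, 20.3-fold lower (adjusted p = 0.0296). Hnmt, the histamine methyltransferase (gene ID 140483, chromosome 2, 24002911 to 24049758), went from 7.52 ± 2.12 to 0.234 ± 0.148 RPKM, 32.1-fold lower (adjusted p = 0.0456). Their log2 differences were −3.53 ± 0.288, −2.90 ± 0.283 and −2.77 ± 0.298 (SE). After median-ratio scaling Hpse2 and Hnmt no longer passed (adjusted p = 0.0663 and 0.0862), nor after quantile normalization (adjusted p = 0.0645 and 0.069). Hnmt was also lost with a pseudocount of 0.1, the filter at 5 RPKM, the replicate block and voom (limma adjusted p = 0.0687, 0.0545, 0.0522 and 0.0556). A gene without a symbol, Entrez gene ID 319269, fell 38.4-fold from 60.4 ± 10.5 to 1.57 ± 0.631 RPKM (log2 difference −4.59 ± 0.289, adjusted p = 0.00862) and was named after its values were seen.

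**Figure D1:**
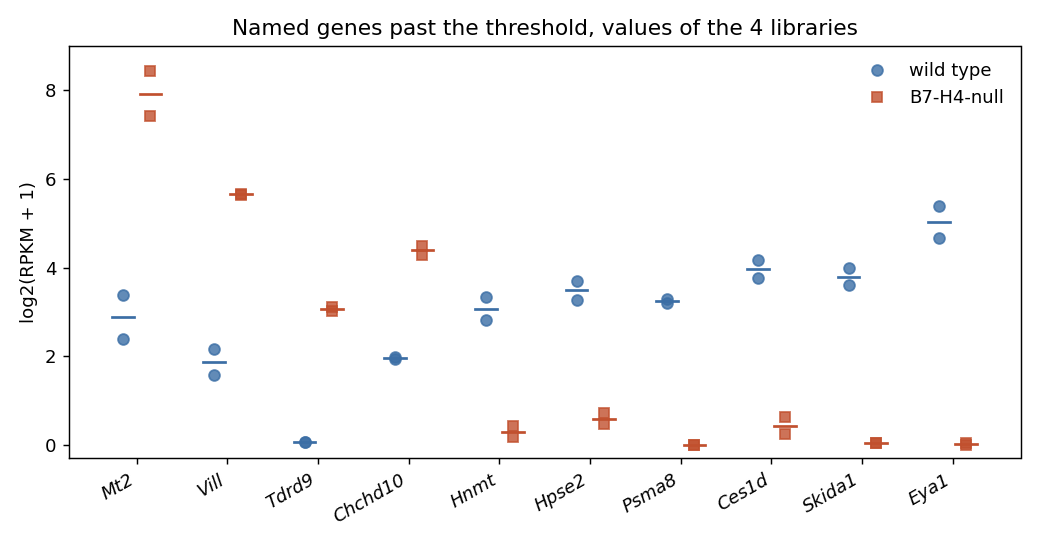
RPKM as log2(RPKM + 1) of the 10 genes named by the fixed rule that passed the test, with 1 point per library and a line at each genotype's mean (n = 2). Mt2, Vill, Tdrd9 and Chchd10 lie higher in both B7-H4-null libraries, and Eya1, Skida1, Ces1d, Psma8, Hpse2 and Hnmt lie lower in both.

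Fewer than 5 genes qualified in the higher direction, and 6 that did not pass fill it. H2-Q6 and H2-Q7, MHC class Ib genes whose reads can be shared between near-identical copies, had means of 2.85 ± 1.48 and 0.973 ± 0.0144 RPKM in wild type and 27.2 ± 2.15 and 7.95 ± 0.775 RPKM in B7-H4-null (adjusted p = 0.0514 and 0.0552). Both passed without wild type replicate 1 (adjusted p = 0.0231 and 0.043), H2-Q6 also without wild type replicate 2 (adjusted p = 0.00441), and both without the mean-variance trend (adjusted p = 0.0475). Flt3, a receptor tyrosine kinase of early progenitors, had 15.9 ± 9.94 against 101.1 ± 2.51 RPKM, a log2 difference of 2.73 ± 0.42 (SE, adjusted p = 0.13). Without wild type replicate 2 Flt3 passed, at 3.37 (adjusted p = 0.00591), and without wild type replicate 1 the difference was 2.09. Gem, a small GTPase, had 0.552 ± 0.102 against 33.5 ± 25.7 RPKM (adjusted p = 0.0691), and passed without wild type replicate 1 or 2 (adjusted p = 0.0164 and 0.0142). Ckm, the muscle creatine kinase, had 5.43 ± 1.57 against 24.4 ± 0.192 RPKM (adjusted p = 0.0859). Tfpi, an inhibitor of the tissue factor pathway, had 2.83 ± 0.713 against 11.8 ± 1.80 RPKM (adjusted p = 0.13).

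At an unadjusted p under 0.05, 612 genes were higher and 872 lower, and 785 and 654 after median-ratio scaling. With no filter on low values, limma called 0 of 20517 genes, with 799 higher and 1088 lower at an unadjusted p under 0.05. Leaving out wild type replicate 1 gave 36 genes higher and 20 lower, and leaving out wild type replicate 2 gave 20 and 9, among them all 12. Without B7-H4-null replicate 1, and likewise without B7-H4-null replicate 2, limma called 0 genes, with 489 higher and 448 lower in the former case and 619 and 857 in the latter at an unadjusted p under 0.05. Both B7-H4-null libraries lay at least 2-fold above both wild-type libraries for 114 genes and at least 2-fold below them for 73. The split of wild type replicate 1 and B7-H4-null replicate 1 against the others gave 44 and 43 such genes and 0 calls, and the remaining split gave 36 and 14 and 7 calls. Libraries of the genotypes did not overlap for 1937 genes in the higher and 3392 in the lower direction. Together these were 44% of genes, against 33.3% by chance for both directions, and the excess lay in the lower direction. The median log2 difference of all tested genes was −0.086, and 0.005 after median-ratio scaling. The counts without overlap were not repeated after that scaling.

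Akt1 and Akt2, kinases of phosphoinositide signalling, did not pass the test. Akt1 had 209.5 ± 20.6 RPKM in wild type against 143 ± 30.7 RPKM in B7-H4-null (SD, n = 2) and Akt2 16.1 ± 1.70 against 10.8 ± 3.24 RPKM, with log2 differences of −0.56 ± 0.277 and −0.56 ± 0.286 (SE, adjusted p = 0.482 and 0.493). Without B7-H4-null replicate 1 these were −0.34 and −0.28, and without B7-H4-null replicate 2 −0.78 and −0.84. Rcor2, a corepressor that partners histone demethylases (chromosome 19, 7267394 to 7275225), had 0.917 ± 0.259 against 4.03 ± 0.0242 RPKM, a log2 difference of 1.40 ± 0.267 (adjusted p = 0.156). Runx1, a transcription factor needed for blood formation, had 8.86 ± 1.77 against 7.03 ± 0.41 RPKM, a log2 difference of −0.29 ± 0.26 (adjusted p = 0.694), or −0.10 without wild type replicate 1 and −0.47 without wild type replicate 2.

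The B7 family ligands and their receptors, 7 tested, had a median of −0.60 (adjusted p = 0.102). The median was −0.38 without wild type replicate 1, −0.31 without B7-H4-null replicate 1 and −0.10 with no filter on low values. Vsir had 87 ± 26.8 against 49.4 ± 2.21 RPKM, Tnfrsf14 4.62 against 7.38 RPKM and Cd80 1.49 against 0.677 RPKM (adjusted p = 0.37, 0.489 and 0.491).

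The leukemia stem cell and self-renewal genes went both ways. Of 25 tested members, 13 lay above 0 and 12 below, with a median of 0.06 (camera adjusted p = 0.39). Fry's test of change in either direction, which does not compare a list with other genes, passed this list (adjusted p = 0.0239), as 1 of 7 lists that passed it. When adjusted over the list alone, 3 were higher and 2 lower, and over all genes only Eya1 passed. The list was called without wild type replicate 1 (median 0.30, adjusted p = 0.0315), and the median was −0.27 without wild type replicate 2 and −0.11 without B7-H4-null replicate 1. Pbx3, a homeobox cofactor, had 70.7 ± 7.79 against 27.5 ± 2.11 RPKM (adjusted p = 0.147), and Cd34, a surface protein of progenitors, had 35.2 ± 10.6 against 71.6 ± 2.21 RPKM (adjusted p = 0.295).

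Of the 31 lists tested, 13 rose and 1, the neutrophil list, fell relative to other genes. With an estimated correlation 0 were called, and fry's directional test called 0. At its preset correlation camera also called 16 lists for the split of wild type replicate 1 and B7-H4-null replicate 2 against the others, and 7 for the remaining split, so a list call here is not particular to the genotype split. No member of a called list passed over all genes tested.

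The secondary and tertiary granule and neutrophil genes, products of late neutrophil maturation, fell. Of 32 tested members, 21 were lower and 1 higher in both B7-H4-null libraries, and 11 were lower when adjusted over the list alone. The median log2 difference was −1.15 (adjusted p = 4.44e-09, and adjusted p = 0.571 with an estimated correlation). Cd177, a surface antigen of neutrophils, had 138 ± 23.6 against 39.5 ± 7.55 RPKM, and Retnlg, a resistin-like secreted protein, 91.9 ± 30.9 against 12.9 ± 7.60 RPKM (both adjusted p = 0.13, and 0.028 for Retnlg without wild type replicate 1). Chil1 had 10.2 ± 2.64 against 1.74 ± 0.865 RPKM, and Mmp9, a gelatinase stored in granules, 45.2 ± 6.56 against 9.27 ± 4.82 RPKM (adjusted p = 0.132 and 0.133). Abundant members, chosen after their values were seen, were S100a8 with 5358 ± 1470 against 2138 ± 844 RPKM, S100a9 with 6580 ± 1970 against 2511 ± 508 RPKM, and Chil3 with 7896 ± 1805 against 2305 ± 1475 RPKM (adjusted p = 0.306, 0.258 and 0.259).

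The primary granule genes, made earlier in granulocyte maturation, rose. Of 14 members, 6 were higher and 1 lower in both B7-H4-null libraries, and 2 were higher when adjusted over the list alone. The median was 0.32 (adjusted p = 0.00258, and adjusted p = 0.59 with an estimated correlation). Mpo, the myeloperoxidase, had 1087 ± 151 against 2771 ± 873 RPKM, Cst7, a cystatin, 41.3 ± 3.03 against 93.3 ± 23.9 RPKM, and Prss57, a serine protease, 44.6 ± 14.4 against 86 ± 16.9 RPKM (adjusted p = 0.256, 0.25 and 0.331). The median was 0.50 without B7-H4-null replicate 1, and 0.18 without B7-H4-null replicate 2, where the call ended (adjusted p = 0.155), as it did after quantile normalization (median 0.15, adjusted p = 0.08).

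**Figure D2:**
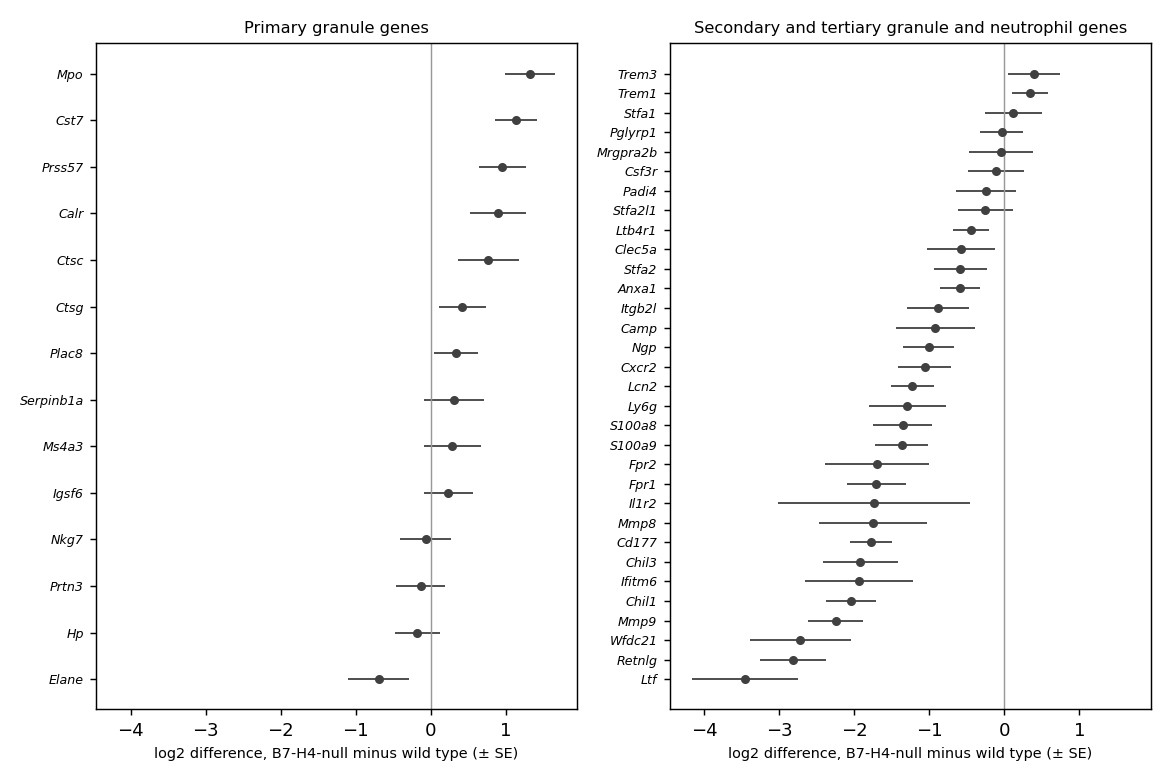
Log2 difference, B7-H4-null minus wild type, on log2(RPKM + 1) with its standard error for the 14 primary granule genes and the 32 secondary and tertiary granule and neutrophil genes (n = 2 per genotype). Mpo lies at 1.32 and Retnlg at −2.82, and the medians of the lists are 0.32 and −1.15.

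The immediate early and stress genes, which respond within minutes to signals and handling, rose. Of 31 members, 23 were higher and 0 lower in both B7-H4-null libraries, and 16 were higher when adjusted over the list alone. The median was 1.63 (adjusted p = 5.13e-19, and adjusted p = 0.571 with an estimated correlation), and without B7-H4-null replicate 1 it was 0.77. Ppp1r15a, a phosphatase subunit of the stress response, had 24.1 ± 11.9 against 235 ± 147 RPKM, Fosl1 0.409 against 4.86 ± 2.20 RPKM, and Atf3 5.33 ± 1.90 against 26 ± 11.6 RPKM (adjusted p = 0.134, 0.134 and 0.147). Ppp1r15a passed without wild type replicate 1 (adjusted p = 0.0231).

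The myeloid lineage transcription factors rose with a median of 0.66 over 27 members. In both B7-H4-null libraries 13 were higher and 2 lower, and 4 were higher when adjusted over the list alone. As written, this list shares Klf2, Klf6, Jun, Junb, Jund, Egr1, Egr2, Egr3 and Nr4a1 with the immediate early list. The rises of these lists are therefore not separate results. Camera gave adjusted p = 3.95e-06, and adjusted p = 0.571 with an estimated correlation. The median was 1.01 without wild type replicate 2 and 0.40 without B7-H4-null replicate 1. Klf2 had 113 ± 50.3 against 509 ± 117 RPKM, Klf4 11.5 ± 2.40 against 143 ± 124 RPKM and Jun 371 ± 76.4 against 1802 ± 1159 RPKM (adjusted p = 0.137, 0.156 and 0.224).

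The NF-kB and inflammatory cytokine genes rose, with a median of 1.14 over 23 members (adjusted p = 3.95e-06, and adjusted p = 0.571 with an estimated correlation). In both B7-H4-null libraries 12 members were higher and 3 lower, and 5 were higher when adjusted over the list alone. The median was 0.46 without wild type replicate 1, 0.56 without B7-H4-null replicate 1 and 0.26 with no filter on low values, and the call held in each. Nfkbiz, a nuclear regulator of NF-kB, had 8.79 ± 0.711 against 47 ± 26.9 RPKM, and the chemokines Ccl9 and Ccl4 had 38.8 ± 17.8 against 137.5 ± 32.7 RPKM and 14 ± 10.8 against 60 ± 16.4 RPKM (adjusted p = 0.15, 0.18 and 0.231), and Ccl4 passed without wild type replicate 2 (adjusted p = 0.0152). Camera did not call the interferon response genes, with a median of −0.24 over 24 members (adjusted p = 0.442). They passed fry's test of change in either direction (adjusted p = 0.0239), which does not compare a list with other genes. Ifih1 had 5.28 against 2.22 RPKM and Gbp3 6.55 against 15.5 RPKM (limma adjusted p = 0.265 and 0.289).

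MHC class I presentation genes rose, with a median of 0.32 over 17 members, 11 higher and 0 lower in both B7-H4-null libraries and 5 higher when adjusted over the list alone. Camera gave adjusted p = 3.95e-06, and adjusted p = 0.571 with an estimated correlation, and the median was 0.53 without B7-H4-null replicate 1. Beside H2-Q6 and H2-Q7, H2-Q4 had 16.3 ± 4.88 against 45.8 ± 21.7 RPKM and H2-K1, a classical class I gene, 282 ± 9.02 against 551 ± 130.5 RPKM (adjusted p = 0.296 and 0.319), and reads may be split among these copies. The dendritic cell and MHC class II genes, 8 tested with Flt3 among them, had a median of 0.12 and were not called (adjusted p = 0.0525). They were called without wild type replicate 2 (median 0.44, adjusted p = 0.00205) and without B7-H4-null replicate 1 (median 0.25, adjusted p = 0.0449).

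The replication-dependent histone genes, whose mRNAs end in a stem-loop in place of a poly(A) tail, rose. Of 51 members, 43 were higher and 0 lower in both B7-H4-null libraries, and 27 were higher when adjusted over the list alone. The median was 0.94 (adjusted p = 4.55e-27, and adjusted p = 0.495 with an estimated correlation). H2bc3 had 2.54 ± 0.864 against 10.4 ± 1.01 RPKM and H1f5 4.90 ± 0.701 against 18 ± 5.63 RPKM (adjusted p = 0.134 and 0.143), and near-identical copies can share such reads. Other RNAs without a poly(A) tail had medians of a similar size but varied more between libraries. The median was 1.11 over 14 genes annotated as snRNAs, 12 of them higher in both B7-H4-null libraries. It was 0.88 over 106 annotated as snoRNAs and scaRNAs, of which 83 lay above 0 and 53 were higher in both. Relative to the wild-type mean, the 106 had medians of 0.35 and −0.35 in the wild-type libraries. Those of the B7-H4-null libraries were 1.19 and 0.72. For histones the wild-type libraries lay at −0.008 and 0.008. The 14 include Snord73b and the U3 genes Rnu3a, Rnu3b1, Rnu3b2, Rnu3b3 and Rnu3b4, which are snoRNAs, so these classes are not separate in kind. Genes of DNA replication, 50 tested, had a median of 0.12 (adjusted p = 0.0865), and mitosis genes, 54 tested, −0.20 (adjusted p = 0.166), with Cenpf, a kinetochore protein, at 8.54 against 4.33 RPKM (adjusted p = 0.32). The replication list was called without wild type replicate 1 (median 0.27, adjusted p = 7.34e-04) and without B7-H4-null replicate 1 (0.17, adjusted p = 0.0131), and was −0.11 without wild type replicate 2. The mitosis list was called lower without wild type replicate 1 (−0.33, adjusted p = 0.0113) and without B7-H4-null replicate 1 (−0.23, adjusted p = 0.00703), and was −0.043 without wild type replicate 2.

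**Figure D3:**
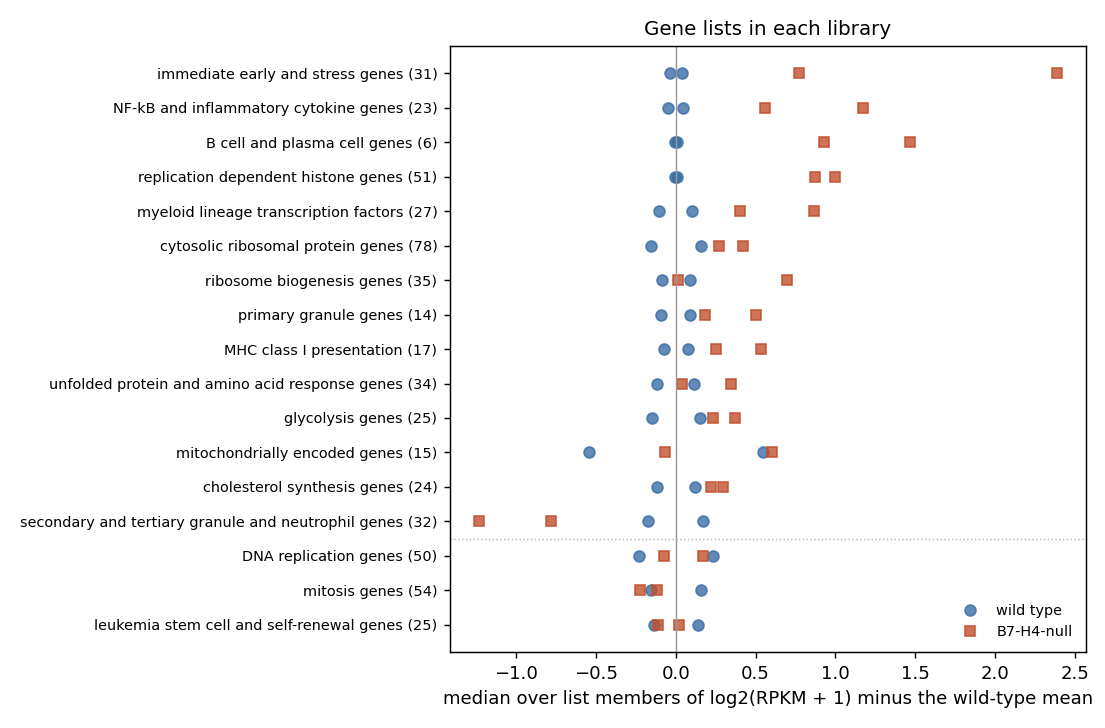
Median over list members of log2(RPKM + 1) minus the wild-type mean, with 1 point per library, for the 14 called lists (above the dotted line) and 3 lists that were not called. The B7-H4-null libraries lie at −1.23 and −0.78 for the neutrophil list and at 2.39 and 0.77 for the immediate early list.

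Cytosolic ribosomal protein genes rose with a median of 0.36 over 78 members, 57 higher and 0 lower in both B7-H4-null libraries (adjusted p = 6.41e-13, and adjusted p = 0.59 with an estimated correlation). When adjusted over the list alone 0 passed, and the median was 0.19 without wild type replicate 1. Rps12 had 29.4 ± 6.36 against 62.1 ± 17.4 RPKM and Rpl3 119 ± 13.6 against 207 ± 23.7 RPKM (adjusted p = 0.307 and 0.329), with pseudogene copies that can take reads. Ribosome biogenesis genes rose with a median of 0.33 over 35 members, 9 higher and 0 lower in both (adjusted p = 3.95e-06, and adjusted p = 0.667 with an estimated correlation), and 0 when adjusted over the list alone. That median was 0.70 without B7-H4-null replicate 1, and 0.01 without B7-H4-null replicate 2, where the call ended (adjusted p = 0.305). Npm1, the nucleolar phosphoprotein, had 146 ± 3.87 against 271 ± 36.3 RPKM and Nop56 60.8 ± 36.1 against 151 ± 61.8 RPKM (adjusted p = 0.306 and 0.337).

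Among metabolic lists, glycolysis genes rose with a median of 0.27 over 25 members, 14 higher and 2 lower in both B7-H4-null libraries and 0 when adjusted over the list alone (adjusted p = 7.09e-05, and adjusted p = 0.571 with an estimated correlation). Slc2a1, a glucose transporter, had 14.3 ± 5.35 against 68.9 ± 42.6 RPKM, Pfkl 21.2 against 44.2 RPKM, and Ldhb 7.81 ± 1.75 against 3.23 ± 0.315 RPKM (adjusted p = 0.228, 0.307 and 0.259). The unfolded protein and amino acid response genes rose with a median of 0.29 over 34 members, 9 higher and 3 lower in both and 1 higher when adjusted over the list alone (adjusted p = 6.09e-04, and adjusted p = 0.571 with an estimated correlation). Their median was 0.11 without wild type replicate 2 and 0.04 without B7-H4-null replicate 2. Phgdh and Psat1, enzymes of serine synthesis, had 3.25 ± 0.103 against 15.3 ± 6.02 RPKM and 40.8 against 78.6 RPKM (adjusted p = 0.137 and 0.319).

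The cholesterol synthesis genes rose with a median of 0.21 over 24 members, 8 higher and 4 lower in both B7-H4-null libraries and 0 when adjusted over the list alone (adjusted p = 0.0234, and adjusted p = 0.594 with an estimated correlation). Insig1, a regulator of sterol sensing, had 10.1 against 17.6 RPKM (adjusted p = 0.474). The median was 0.36 without wild type replicate 1, and the call ended without wild type replicate 2 (median 0.01, adjusted p = 0.441) and without B7-H4-null replicate 2 (median 0.22, adjusted p = 0.099). The mitochondrially encoded genes, called higher with a median of 0.26 over 15 members (adjusted p = 0.0234, and adjusted p = 0.699 with an estimated correlation), had 0 members apart from both wild-type libraries and 0 past the test when adjusted over the list alone. Their median was 0.79 without wild type replicate 1, −0.12 without wild type replicate 2, −0.07 without B7-H4-null replicate 1 and 0.60 without B7-H4-null replicate 2, and after quantile normalization the call ended (median 0.19, adjusted p = 0.247). Nuclear oxidative phosphorylation genes, 73 tested, had a median of 0.04 (adjusted p = 0.0865), and after median-ratio scaling the list was called (median 0.14, adjusted p = 0.0182). It was also called without wild type replicate 2 (0.18, adjusted p = 0.00347) and without B7-H4-null replicate 1 (0.24, adjusted p = 2.29e-04), and its median was −0.088 without wild type replicate 1 and −0.12 without B7-H4-null replicate 2.

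The B cell and plasma cell genes, a check for other cell types, rose with a median of 0.99 over 6 members, 4 higher and 0 lower in both B7-H4-null libraries and 3 higher when adjusted over the list alone (adjusted p = 9.99e-04, and adjusted p = 0.571 with an estimated correlation). Ighm, the mu heavy chain, had 15.7 ± 8.04 against 64.9 ± 5.39 RPKM and Vpreb1, a surrogate light chain of early B cells, 0 and 0.131 against 1.66 and 2.05 RPKM (adjusted p = 0.143 and 0.173), and Ighm passed without wild type replicate 1 (adjusted p = 0.0248). The call ended without B7-H4-null replicate 2 (median 0.93, adjusted p = 0.391) and without the filter on low values (median −0.001, adjusted p = 0.173).

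Lists tied to survival signalling were not called. The FOXO target genes, 22 tested, had a median of 0.02 (adjusted p = 0.442) and the BCL2 family and caspases, 28 tested, −0.22 (adjusted p = 0.484). The cyclin dependent kinase inhibitors and p53 targets, 24 tested, had a median of −0.17 with a mean of 0.002 (adjusted p = 0.894). Pmaip1, the p53 target Noxa, had 72.1 against 233 RPKM, Trp53inp1 10.2 against 2.29 RPKM, and Xiap, a caspase inhibitor, 15.8 against 7.17 RPKM (adjusted p = 0.196, 0.164 and 0.254), and Trp53inp1 passed without wild type replicate 1 (adjusted p = 0.0465).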

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

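Limma on voom weights and the fit of protein-coding genes alone were chosen after seeing the data, and the other alternatives were fixed before. Over the 91 genes compared, 1180 of 1257 comparisons kept their direction and side of the threshold, 42 lost the threshold, 32 gained it and 3 reversed. Most of the 91 genes were not called in the first place, and staying uncalled counted as kept. The 42 losses could fall only on called genes, so the 1180 do not measure how stable the calls were. Over the 31 lists, 348 of 428 comparisons kept both, 38 lost the threshold, 24 gained it and 18 reversed. Of the 12 called genes, limma shared 11 with a pseudocount of 0.1, 11 with the filter at 5 RPKM, 10 after either other scaling, 12 without the trend or with robust variances and 10 with voom. Hnmt was the gene lost most often, Hpse2 was lost under both scalings (adjusted p = 0.0663 and 0.0645), and Chchd10 under voom (adjusted p = 0.0603). At this depth and with 2 libraries per genotype, 2-fold changes are mostly missed.

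The 5 genes higher became 28 with robust variances, 0 without a filter, 12 with the replicate block and 0 to 36 with a library left out. The 7 genes lower became 23 with robust variances, 0 without a filter and 0 to 20 with a library left out. Without a filter 20517 genes were tested, with 799 higher and 1088 lower at an unadjusted p under 0.05. Same-numbered libraries deviated together to some extent, with a correlation of deviations across genes of 0.247. The mitochondrially encoded share of the RPKM sum was 6.45 and 3.47% in wild type replicates 1 and 2. In B7-H4-null replicates 1 and 2 it was 6.9 and 4.29%. Xist was also close between same-numbered libraries. The labels do not tie these libraries, and 2 numbers are too few to show a pairing. With the number as a replicate block, 11 of the 12 called genes were shared, Hnmt no longer passed (adjusted p = 0.0522), and of the other genes compared Ppp1r15a, Retnlg and Vcam1 passed (adjusted p = 0.0202, 0.0287 and 0.0445). The 114 genes at least 2-fold higher became 190 with a pseudocount of 0.1 and 74 with the filter at 5 RPKM. The 73 genes at least 2-fold lower became 165 and 42, and 44 among protein-coding genes alone. The 13 lists higher became 0 with an estimated correlation and 0 with fry's directional test. The 1 list lower became 0 in both, 2 with no filter, with a pseudocount of 0.1 or with the replicate block, and 2 to 3 with a library left out. The added lists were the mitosis genes with no filter (median −0.20, adjusted p = 0.0422), the megakaryocyte genes with a pseudocount of 0.1 (−0.72, adjusted p = 0.0471) and the cytokine receptors with the block (−0.32, adjusted p = 0.0391). The cause of these changes was not tested, beyond fewer or more genes tested where the filter changed.

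For the Vtcn1 log2 difference, B7-H4-null minus wild type, 0.05 became 0.46 with a pseudocount of 0.1 and 0.05 to 0.057 with a library left out. Directions reversed, none of them of a called result except the mitochondrially encoded list, with the filter at 5 RPKM for the p53 list (median −0.11) and the interferon list (−0.14), with fry for the leukemia stem cell list (median 0.059, where fry and camera differ in direction), and with a library left out. The ranges in the last case were −1.16 to 0.45 for Kit, −0.38 to 0.38 for Xist, −0.12 to 0.79 for the mitochondrially encoded genes, −0.11 to 0.27 for DNA replication, −0.24 to 0.086 for FOXO targets, −0.27 to 0.30 for the leukemia stem cell list, −0.29 to 0.29 for monocyte genes and −0.12 to 0.24 for oxidative phosphorylation. Camera's direction reversed while the median kept its sign for the BCL2 list (−0.35 to −0.17), the p53 list (−0.30 to −0.05), the interferon list (−0.30 to −0.13) and the mitosis list (−0.33 to −0.043). The cause was not tested.

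With an estimated correlation and with fry's directional test no list was called, while fry's test of change in either direction passed 7 of 31. These tests leave the medians as they are. The medians were 0.94 for histones, 1.63 for immediate early genes, 0.36 for ribosomal proteins and −1.15 for neutrophil genes. They were 0.66 for myeloid factors, 0.32 for MHC class I, 1.14 for NF-kB, 0.33 for ribosome biogenesis and 0.27 for glycolysis. For the unfolded protein and amino acid response the median was 0.29, and for B cell genes 0.99. It was 0.32 for primary granules, 0.21 for cholesterol synthesis and 0.26 for mitochondrially encoded genes. Calls also ended with no filter for B cell genes (−0.001) and mitochondrially encoded genes (0.26), with quantile normalization for the latter (0.19) and primary granules (0.15), and with the filter at 5 RPKM for cholesterol synthesis (0.21). Lists gained a call after median-ratio scaling for oxidative phosphorylation (0.14), with voom for dendritic cell and MHC class II genes (0.13), and among protein-coding genes for these (0.24), oxidative phosphorylation (0.16) and DNA replication (0.23). With a library left out, calls changed for B cell genes (0.86 to 1.47), cholesterol synthesis (0.012 to 0.36), primary granules (0.18 to 0.50), ribosome biogenesis (0.013 to 0.70), cytokine receptors (−0.70 to −0.17), dendritic cell and MHC class II genes (−0.12 to 0.44), mast cell genes (−0.036 to 1.16) and megakaryocyte genes (−0.79 to −0.33). The cause was not tested. The test planned for raw counts was not run, since the table holds RPKM.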

Other observations

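The tests on S phase, on depth and on called genes near Vtcn1 were chosen after the results they measure were seen, and the test on other RNAs without a poly(A) tail after the histone values but before its own result. Among monocyte and macrophage genes, Cd68, a lysosomal glycoprotein, had 62 ± 2.04 RPKM in wild type and 143 ± 6.18 RPKM in B7-H4-null, and Cx3cr1, the fractalkine receptor, 0.0537 against 1.44 RPKM (SD, n = 2, limma adjusted p = 0.18 and 0.258). The list of 29 had a median of −0.09 and a mean of 0.06, of opposite sign, and was not called (camera adjusted p = 0.236), except higher without wild type replicate 2 (median 0.29, adjusted p = 0.0015) and without B7-H4-null replicate 1 (0.26, adjusted p = 0.0106). Cpa3, a mast cell protease, had 4.93 against 38 RPKM and Gata2, a factor of progenitors and mast cells, 9.06 RPKM against 66.9 and 17.9 RPKM in the B7-H4-null libraries (adjusted p = 0.207 and 0.319), and Cpa3 passed without wild type replicate 2 (adjusted p = 0.02). The mast cell, basophil and eosinophil list had a median of 0.01 and a mean of 0.56 over 9 members (adjusted p = 0.0887), and it was called without wild type replicate 2 (median 0.48, adjusted p = 0.0354) and without B7-H4-null replicate 2 (1.16, adjusted p = 3.25e-04).

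Stromal and endothelial genes went both ways. Eng, a TGF-beta coreceptor, had 4.92 against 0.989 RPKM and Vcam1, an adhesion ligand, 61.5 ± 44.6 against 6.87 ± 8.14 RPKM, while Pecam1, an adhesion molecule, had 17.1 ± 0.913 against 34 ± 4.31 RPKM and Spp1, osteopontin, 2.56 against 5.83 RPKM (adjusted p = 0.137, 0.273, 0.259 and 0.336). The 10 stromal and endothelial genes had a median of −0.32 (camera adjusted p = 0.484), −0.098 without B7-H4-null replicate 1 and −0.55 without B7-H4-null replicate 2. They passed fry's test of change in either direction (adjusted p = 0.024). Gng11, listed with the megakaryocyte genes, had 33 against 15.2 RPKM (adjusted p = 0.215), and those 6 genes a median of −0.43 (adjusted p = 0.0968), called without wild type replicate 2 (−0.79, adjusted p = 0.0382). The 30 cytokine and growth factor receptors had a median of −0.32 (adjusted p = 0.0849), called without wild type replicate 1 (−0.70, adjusted p = 0.00594) and without B7-H4-null replicate 2 (−0.50, adjusted p = 0.0163), and the 21 adhesion and homing receptors 0.02 (adjusted p = 0.251, and −0.047 to 0.13 with a library left out). Too few members for a test were left of the sort markers (3, median −0.49), the erythroid genes (4, median −0.06), the T and NK cell genes (3, median −0.04) and the X inactivation and Y-linked genes (2, median 0.02). Xist had 64.5 and 37.7 RPKM in wild type replicates 1 and 2 and 64.1 and 38.0 RPKM in B7-H4-null replicates 1 and 2. It thus differed by replicate number and not by genotype.

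Replication-dependent histone genes had a median log2 difference of 0.94, and 120 genes for snRNAs, snoRNAs and scaRNAs, which also lack a poly(A) tail, one of 0.95. Some of the 120 rest on few reads, such as Rnu12 and Snord82, chosen after their values were seen, with 0 reads in wild type. Whether reads on the 120 came from the small RNAs or from overlapping transcripts was not tested. A larger share of cells in S phase cannot be told apart as a source of the histone values: the DNA replication list had a median of 0.12 (0.27 without wild type replicate 1), and its bootstrap range over genes, −0.02 to 0.18, lay under 0.31, the level chosen for this test from the histone median, but its bound from the spread between libraries, −0.48 to 0.57, did not. More carry-over of RNA without a poly(A) tail in the B7-H4-null libraries may account for both classes. Between the 2 wild-type libraries, however, the classes did not move together. Their medians there were −0.008 and 0.008 for histones, 0.35 and −0.35 for snoRNAs and scaRNAs, and 0.14 and −0.14 for snRNAs. Carry-over was tested on other RNAs without a poly(A) tail. Of these 4 were tested, Rpph1, Rmrp, Rny1 and Vaultrc5, fewer than the 5 required in advance, with a median of 0.79 at percentile 99.65 of 10000 random lists matched on mean expression, so this too stays open. Library preparation and genotype cannot be separated with these 4 libraries, and a difference by genotype was not tested.

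Neutrophil genes, of which the most abundant were Chil3 (7896 against 2305 RPKM) and S100a9 (6580 against 2511 RPKM), fell with a median of −1.15, while primary granule genes rose with a median of 0.32. With an estimated correlation camera called neither list (adjusted p = 0.571 and 0.59). A smaller share of mature neutrophils among the sorted cells was taken to lower all abundant members alike. That holds only if no other sorted cell made them, which was not tested. Of the 24 members with a wild-type mean of at least 20 RPKM, 2 lay above 0 and 17 below −0.5. They ran from −3.46 for Ltf (−4.15 without wild type replicate 2), chosen after its values were seen, to 0.40. Neither bound set in advance was met, so such a share and a change within the leukemia cells cannot be told apart. The sort for c-Kit would remove most mature neutrophils if it was clean, which was not tested. The depths of the genotypes overlapped, with a ratio of mean totals of 1.01. RPKM values are already scaled to these totals, so this comparison says little about the neutrophil genes.

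Near-0 genes, with both libraries of a genotype at 0.3 RPKM or less and both of the other at 3 RPKM or more, numbered 8, among them Eya1, Skida1, Psma8 and Tdrd9. Also among them was Rnu12, a small RNA with 15 and 7 reads in the B7-H4-null libraries. A930004D18Rik (chromosome 2, 18025187 to 18037741), named after its values were seen, lies close to Skida1 (18044087 to 18048449). The 8 may therefore not all be independent. A segment of another strain around the targeted locus is argued against for these 8 by their positions, as 0 lie within 20 Mb of Vtcn1. It stays open for Gm128, 1 of the 11 called genes with a coordinate, which lies 5.58 Mb from Vtcn1 and missed the near-0 limit with 0.335 RPKM in wild type replicate 1 (exact one-sided hypergeometric p = 0.227 for the 11). Separate leukemia clones in every library, each with genes on or off by chance, may account for part of the 8, since the other splits of the 4 libraries gave 4 and 6 such genes. An effect of the genotype stays open and untested. The labels do not say whether libraries of a genotype came from separate leukemias. A clone shared by both libraries of a genotype could not be told apart from the genotype.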
